A study of Homo sapiens with 3 samples.

How the data were processed

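Total RNA from HK-2 cells, an immortalised human renal proximal tubular epithelial line, was measured on nylon cDNA expression arrays with a 32P label, per the labels' protocols. The cells were grown for 72 h, moved for 48 h to growth medium set by bis-Tris (12.5 mM) to 1 of 3 values, pH 7.4, pH 7.0 or pH 6.7, and then kept for 24 h in serum-free medium at the same pH before RNA isolation, per the labels' protocols. The RNA of 3 isolations was pooled for each pH, per the series' design text. Each pH was therefore represented by 1 array of 1 pool. Pooling averages the isolations, so the spread between them cannot be seen.

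The deposited table held 243 features on each of the 3 arrays, as linear intensity values that were all whole numbers above 0. The image scanner, the background correction, the software and the normalization used by the authors are not given in the sources used here. The values themselves bear on the normalization. The highest column total exceeded the lowest by 0.0692%. In addition, each column lay on a regular lattice: all 222 values under 3000 on the pH 7.4 array and all 222 on the pH 7.0 array were whole multiples of 2.00 and 1.975, with fractions cut off, and all 223 on the pH 6.7 array were such multiples of 1.58. Without a lattice about 50.0%, 50.6% and 63.3% of whole numbers would fit these steps, 1 simulated column with no lattice fitted its best step in 61.7% of its values, and a column made with a known step returned that step. In the values tested, each deposited column is thus a column of whole numbers multiplied by 1 factor, 0.987 for pH 7.0 and 0.79 for pH 6.7 relative to pH 7.4. The factor is taken to hold for the brighter values too, which were not tested. Such scaling makes total brightness equal by construction, so a change shared by all features cannot be seen.

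An annotation of the array platform was not used here, so the array codes are not tied to genes. Of the 243 codes, 151 began with S, 17 with C, and 75 were digits only. Although 61 of the digit codes equalled some gene number and 33 codes equalled some gene synonym in the human RefSeq gene table, no code equalled a gene symbol, and no source used here says that the codes are gene numbers or names, so those matches were not used. The 17 gene lists fixed before the data were examined (chaperones, endoplasmic reticulum stress, antioxidant enzymes, xenobiotic metabolism, metallothioneins, DNA repair, p53 response, cell cycle, apoptosis, MAP kinases, inflammation, acid-base handling, proteasome, housekeeping genes, and fibroblast, leukocyte and endothelial markers) could therefore not be applied, nor could scaling to housekeeping genes. No genome coordinates are given for the same reason.

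Differences between arrays were computed as log2(intensity + pseudocount), with the pseudocount at the 10th percentile of all values, 229 intensity units. This understates the change of dim features: a true doubling from an intensity of 500 reads as 1.69-fold, and a change of 2.46-fold is needed there to reach the 2-fold threshold. Plain ratios of the deposited intensities are given beside the pseudocount values. Features were also described in 3 classes chosen after the data were seen: 10 bright features with a mean intensity of at least 10000, 61 intermediate features from 1000 upwards, and 172 dim features. With 1 array per pH no test of one pH against another is possible. A linear trend on pH over the 3 arrays leaves 1 residual degree of freedom per feature. It was added after the data were seen and fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. It was simulated on the pseudocount scale with 243 features and 1 noise SD for all of them, 40 being given a 4-fold trend. It recovered 100% of these at a noise SD of 0.1 and 91.2% at 0.273, the SD of the observed values around their means. The largest observed difference on that scale was 2.26-fold, so recovery of changes of the observed size was not measured. The number of arrays limits the precision of every value.

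The comparisons and the threshold were fixed before the data were examined, as was the rule for the features named: those with the largest changes past 2-fold against pH 7.4, and at most 2 that were higher and 2 that were lower where no gene names are at hand. As a yardstick, 1000 sets of 3 arrays without any pH effect were simulated, with each feature's spread set to the average within-feature spread over the 3 arrays in its tertile of brightness. This spread includes any real pH effect, so the simulation shows what unstructured variation of the observed size would give and cannot separate noise from response. All 3 simulated arrays had equal spread. The observed arrays did not. The SD of each array's own deviations was split from the variances of the 3 differences. On the pseudocount scale it was 0.29 at pH 7.4, 0.21 at pH 7.0 and 0.31 at pH 6.7. By plain ratios it was 0.50, 0.36 and 0.45. The simulated ranges for order, middle place and correlation hold only for arrays of equal spread. The calling step was tested on simulated data for pH 6.7 against pH 7.4 over 243 features, with 40 changed features per draw, 100 draws and a noise SD of 0.1 on the log2 scale. It recovered 5.2% of 2-fold, 58.9% of 3-fold, 74.5% of 4-fold and 81.4% of 6-fold changes, and called 0% of unchanged features, which noise of that size could hardly bring to 2-fold. With noise of the observed within-feature spread it recovered 25.8% of 2-fold, 56.0% of 3-fold, 74.7% of 4-fold and 86.0% of 6-fold changes, and called 1.97% of unchanged features. At the noise SD of 0.1, among features of mean intensity 1000 or more, it recovered 18.6% of 2-fold and 98.0% of 3-fold changes.

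The alternatives were median centring, quantile normalization, no pseudocount, a pseudocount at the 25th percentile (322), a filter on dim features, and thresholds of 1.5-fold and 3-fold. A total without the bright features, removal of the authors' scaling, and a lowess fit with a span of 0.5 were added after the data were seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.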

Results

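Stress-related transcripts were profiled in HK-2 cells, a human proximal tubular cell line, held at pH 7.4, pH 7.0 or pH 6.7, with 1 array of pooled RNA per pH. The series asks how the expression of stress-related genes in these cells depends on the pH of the medium. Each array measured 243 features. The total intensity was 623158 at pH 7.4, 622959 at pH 7.0 and 623390 at pH 6.7, and the median feature stood at 498, 472 and 497. There are no replicates, so every difference between 2 arrays carries no replicate error. The 3 pH values allow 1 weak test, a linear trend, reported with the order of the arrays. The array codes are printed as deposited, without gene names.

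A small set of bright features held most of the signal. The 10 features with a mean intensity of at least 10000 made up 67.1% of the total at pH 7.4, 68.5% at pH 7.0 and 65.4% at pH 6.7. The features were ranked similarly on the 3 arrays. Across features, which are not independent replicates, Spearman's rho was 0.852 between pH 7.4 and 7.0, 0.838 between pH 7.4 and 6.7, and 0.867 between pH 7.0 and 6.7. Among the 172 dim features the corresponding values were 0.594, 0.569 and 0.643.

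Few features at pH 7.0 differed 2-fold from pH 7.4 on the pseudocount scale. Of 243 features, 1 was at least 2-fold higher and 0 were at least 2-fold lower, while 217 features (89.3%) lay within 1.5-fold, or 174 (71.6%) by plain ratios. The higher one was feature S133, which stood at 36 at pH 7.4, the lowest value on that array, and at 351 at pH 7.0. Its pseudocount difference was 1.13 on the log2 scale, and the plain ratio was 9.75-fold. That ratio is uncertain, because the background correction is unknown and a value of 36 is not shown to lie above background. At pH 6.7 the same feature stood at 268, a log2 difference of 0.91 from pH 7.4. The 10 bright features all lay within 1.5-fold at pH 7.0, as did 57 of the 61 intermediate features, or 52 by plain ratios. Whether the brightest spots had reached an upper limit of the reading was not tested. Such a limit would narrow their differences before scaling. As the pH 6.7 array was then scaled down, the limit would read as falls there. The highest value was 60402 at pH 7.4, 62721 at pH 7.0 and 50130 at pH 6.7. Features 761, S43 and 16, the brightest at pH 7.4, had log2 ratios of -0.27, -0.32 and -0.42 at pH 6.7 against pH 7.4. Of the 10 bright features, 6 were lower there and 4 higher. A limit and a true fall were not separated. By plain ratios, 12 features were at least 2-fold higher and 11 at least 2-fold lower at pH 7.0, and all 23 belonged to the dim class. In simulated arrays with no pH effect, the median count was 5 on the pseudocount scale (95% of simulations from 1 to 9) and 25.5 by plain ratios (17 to 35).

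At pH 6.7, 1 feature was at least 2-fold higher and 4 were at least 2-fold lower than at pH 7.4, and 204 features (84.0%) lay within 1.5-fold, or 165 (67.9%) by plain ratios. The higher one was feature S45, an intermediate feature at 1342 at pH 7.4, 1992 at pH 7.0 and 3329 at pH 6.7. This is a plain ratio of 2.48-fold at pH 6.7 and a log2 difference of 1.18 with the pseudocount. On the pseudocount scale the widest difference downwards was that of feature 365, with a log2 difference of -1.13. It stood at 1564, 1190 and 589 in the same order, a plain ratio of 2.66-fold lower. Feature 14, a dim feature, stood at 434, 211 and 93, a plain ratio of 4.67-fold lower at pH 6.7 and a log2 difference of -1.04. Its ratio is uncertain too, since 93 is well under the pseudocount and not shown to lie above background. The remaining 2 lower features, 1 intermediate and 1 dim, stood 2.22-fold and 3.23-fold lower by plain ratios. Within 1.5-fold on the pseudocount scale lay 8 of the 10 bright, 45 of the 61 intermediate and 151 of the 172 dim features. The corresponding numbers by plain ratios were 8, 44 and 113. By plain ratios 17 features were at least 2-fold higher and 11 at least 2-fold lower. Of these, 23 were dim, 5 intermediate and 0 bright. The simulated arrays with no effect gave a median of 5 features on the pseudocount scale (1 to 9) and 25 by plain ratios (17 to 34), and the observed numbers lay within these ranges. The simulated spread was taken from these same arrays, any pH effect included, so counts near the observed ones follow by construction. The excess of lower over higher features at 2-fold on the pseudocount scale was not found by plain ratios, where higher features were more numerous. Nor was it found at 1.5-fold on the pseudocount scale, with 24 higher and 15 lower. With the pseudocount at the 25th percentile 1 was higher and 1 lower. The excess also takes the arrays as equal in total. Relative to pH 7.4, the deposited scaling lowered every value of the pH 6.7 array by 1 factor. With that factor removed, which moves all features up together, 14 features were higher and 0 lower, and 1 of the 5 features stayed past 2-fold.

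**Figure D1:**
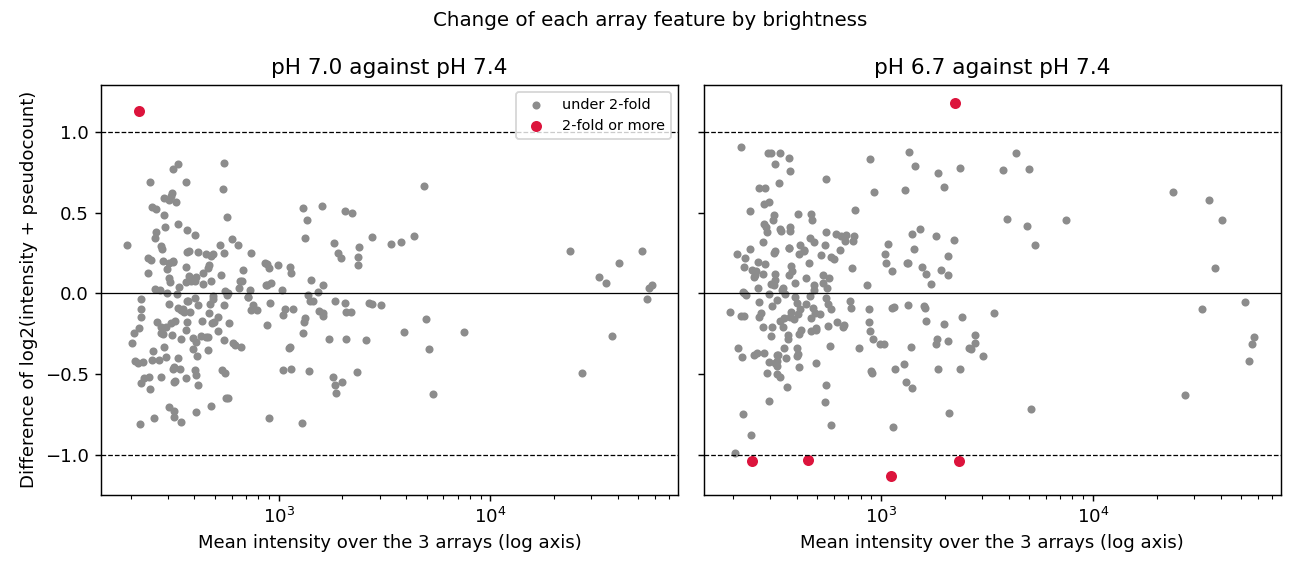
Difference of log2(intensity + 229) between the acid array and the pH 7.4 array (vertical axis) against the mean intensity over the 3 arrays (horizontal log axis), with 1 point for each of the 243 features and dashed lines at 2-fold. In the pH 7.0 panel 1 dim feature lies beyond the lines, and in the pH 6.7 panel 1 feature lies above and 4 lie below them.

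Between the 2 acid arrays, 0 features differed 2-fold on the pseudocount scale. The largest difference upwards at pH 6.7 relative to pH 7.0 was 1.92-fold and the largest downwards was 1.74-fold on that scale. By plain ratios 7 features were at least 2-fold higher and 8 at least 2-fold lower at pH 6.7. The simulated arrays gave a median of 5 (1 to 9) on the pseudocount scale and 25 (16 to 35) by plain ratios, so both counts lay just under the simulated ranges. The pH 7.0 array had the smallest own SD of the observed arrays, and ranges simulated with equal spread do not allow for this.

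The features past 2-fold at pH 6.7 were ordered by pH. Features S45, 365 and 14 each had their pH 7.0 value between the other two, as did the remaining 2, so that 5 of 5 ran in 1 direction from pH 7.4 to 6.7. Simulated arrays without an effect gave a median of 4 such features (1 to 8), because a feature picked for a wide gap between the outer arrays often has its middle array inside that gap. Over all 243 features, 46 were higher and 46 lower at each step towards acid medium, 92 in all or 37.9%, where 3 exchangeable arrays would give 81 features (33.3%) and the simulated range was 67 to 95. By plain ratios 25 of the 28 features past 2-fold at pH 6.7 were ordered, against a simulated median of 18 ordered features (11 to 26). The ordering was thus not beyond the simulated ranges. A linear trend of log2 intensity on pH, fitted with limma over the 3 arrays with 1 residual degree of freedom per feature, passed an adjusted p of 0.05 (Benjamini-Hochberg over 243 features) for 0 features. The smallest adjusted p in limma was 0.497, which features S45, 365 and 14 shared with others. At an unadjusted p under 0.05 limma gave 19 features, 11 higher and 8 lower in acid medium, where chance gives 12.2. With the pH 7.4 or the pH 6.7 array put in the middle instead, the same fit gave 6 and 2 features. These counts cannot weigh the orders against each other. The pH 7.0 array had the smallest own SD, 0.21 against 0.29 at pH 7.4 and 0.31 at pH 6.7. That alone leaves the least error when it is in the middle. The prior degrees of freedom in limma also differed, at 5.9, infinite and 2.9 with pH 7.0, 7.4 and 6.7 in the middle. Any departure from a straight line counts as error in this fit.

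**Figure D2:**
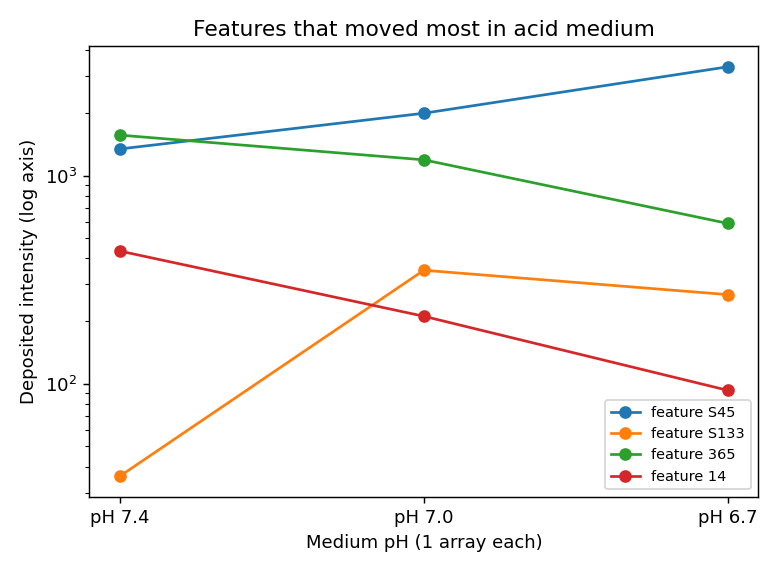
Deposited intensity (vertical log axis) of 4 features at pH 7.4, 7.0 and 6.7, with 1 array per point and no error bars because there are no replicates. Features S45, 365 and 14 run in 1 direction with acidity, while feature S133 goes from 36 to 351 and then to 268.

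By plain ratios the spread of the differences was widest among dim features. On that scale the SD of the log2 difference between pH 6.7 and pH 7.4 was 0.72 over the 172 dim, 0.57 over the 61 intermediate and 0.44 over the 10 bright features. Between pH 7.0 and pH 7.4 the values were 0.69, 0.38 and 0.24. On the pseudocount scale, which narrows the differences of dim features, the SDs between pH 6.7 and pH 7.4 were 0.39, 0.50 and 0.44, so the dim features were the narrowest there, while between pH 7.0 and pH 7.4 they were 0.37, 0.34 and 0.24. Among the 71 features with a mean of at least 1000, the pH 6.7 array held the middle value for 13 features, against 27 for pH 7.4 and 31 for pH 7.0, where an even division gives 23.7. Among the 172 dim features the counts were 63 for pH 6.7, 46 for pH 7.4 and 61 for pH 7.0, where an even division gives 57.3.

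The changes at pH 7.0 and at pH 6.7, both taken against the same pH 7.4 array, were correlated across the 243 features with Pearson's r = 0.56 and Spearman's rho = 0.54, and 69.96% of features had the same sign. A shared control produces such a correlation with no effect at all: the simulated arrays gave a median r of 0.50 (0.40 to 0.60), a median rho of 0.48 (0.37 to 0.58) and 66.7% of equal signs (60.9 to 72.4%). The covariance was 0.0843 and the simulated covariance 0.0861 (0.0634 to 0.115). The observed covariance equals the pH 7.4 array's own variance, and the simulated spread was taken from these same arrays. Their nearness therefore carries no weight. By plain ratios, 7 features were 2-fold higher on both acid arrays and 1 was 2-fold lower on both, where independent lists would share 0.84 and 0.50. The simulated arrays, which share their control but hold no effect, gave a median of 4 in each direction (1 to 8), and both counts lay within that range. With 1 control array, the control could not be split.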

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

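Each pH had 1 array, so no replicate could be left out. No paired analysis was possible because the groups share no second replicate. The planned scaling to housekeeping genes and all gene list results were not run, since the codes carry no gene names. Median centring, quantile normalization, the total without the bright features and the lowess fit gave 4 or 5 features at pH 6.7 against pH 7.4, 1 at pH 7.0, 0 between the acid arrays and 4 or 5 ordered by pH, within 1.5 times the values reported. Without a pseudocount the counts became 23 at pH 7.0, 28 at pH 6.7, 15 between the acid arrays and 25 ordered by pH, and r became 0.599. The split at pH 6.7 went from 1 higher and 4 lower to 17 higher and 11 lower, because dim features then pass. With the 25th percentile as the pseudocount, 0 features passed at pH 7.0, 2 at pH 6.7 and 2 were ordered. Restricting the data to the 122 features at or above the median mean intensity left 0, 3 and 3, with r = 0.498. At 1.5-fold the counts were 26, 39, 29 between the acid arrays and 33 ordered, and at 3-fold they were 0 at pH 7.0, 0 at pH 6.7 and 0 ordered. The 39 at pH 6.7 were 24 higher and 15 lower. Removing the authors' scaling gave 14 features at pH 6.7, 7 between the acid arrays and 10 ordered, all higher, with 1 of the 5 reported features at pH 6.7 still past 2-fold. It moves every pH 6.7 value up by 1 factor, 1.27 relative to pH 7.4, and the median log2 difference of all features to 0.22, so a shift of the counts upwards follows from its construction. The limma trend, added after the data were seen, passed for 0 features with no pseudocount, median centring or the scaling removed as well, with smallest adjusted p between 0.0816 and 0.497. In these fits 19 to 29 features reached an unadjusted limma p under 0.05. They were 10 higher and 9 lower in acid medium with no pseudocount, 14 and 8 with median centring, and 25 and 4 with the scaling removed. No named feature changed direction against pH 7.4 at pH 6.7 under these settings. Feature S45 stayed past 2-fold in all of those at the 2-fold threshold, while feature 14 fell inside it in 4, with log2 differences of -0.87 to -0.97, and feature 365 did so only with the scaling removed (-0.87). The filter on the mean left out features S133 and 14. Brightness limits all of this, since a dim feature needs a wider change to pass.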

Other observations

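The tests of an explanation below were set down before the value each measures was seen, but after the table had been looked through. The brightness classes and the pattern of the pH 6.7 array were picked from the data.

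Undoing the lattice shows the brightness of the arrays before scaling. The total on the pH 6.7 array was 1.27 times that of the pH 7.4 array and the total on the pH 7.0 array 1.01 times. All 243 values of the pH 7.4 array were even, as its step of 2.00 gives, against 124 on the pH 7.0 array and 115 on the pH 6.7 array. Whether the pH 7.4 array served as the reference of the scaling was not tested. Whether the brighter pH 6.7 array reflects exposure, labelling or more stress-related transcript per unit of RNA was not tested. Total scaling removes the difference in total in any case. It does not remove a difference in how the total is divided between bright and other features.

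A first pattern is that the pH 6.7 array stood apart among the 71 features of mean intensity 1000 or more, where it held the middle value for 13 features. This did not hold among the 172 dim features, where the pH 6.7 array was in the middle for 63, the pH 7.0 array for 61 and the pH 7.4 array for 46. A lowess fit of each array against the array mean, which would remove an intensity-dependent shift, still left it in the middle for 14 features. This is below the 15.7 that marks an even division minus 2 binomial standard errors. Centring on the median of these features, which would remove an offset left by total scaling, gave 14 as well. Neither correction thus removed the pattern, though the margins under the bound were narrow. The total without the bright features gave 15. The 13 as deposited were all intermediate features, 13 of 61 where an even division gives 20.3. Among the 10 bright features the count was 0, where an even division gives 3.3. A biological effect of pH 6.7, larger random error on that single array, and chance in a pattern picked from the data all remain open. So does an upper limit of the reading for the brightest spots, which scaling would turn into falls at pH 6.7. Without a second array these explanations could not be separated. Features are not independent, so the binomial error is itself a minimum.

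A second pattern is the order of the arrays, for which a candidate explanation is a response graded by pH. The pH 7.0 array lay in the middle for 92 of 243 features, above the 81 of an even division and short of the 95.7 set beforehand, so a graded response and unordered variation cannot be told apart by this count. The count ran from 86 to 101 over the scalings of the 243 features. The 101, with the authors' scaling removed, passes the bound and the others do not. Removing the scaling lifts every value of the pH 6.7 array by the same factor. Such a lift moves that array outwards and can raise the count with no graded response. The bound, set around an even division, does not allow for this, so the 101 cannot decide the question either.

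Another pattern is the wider spread of plain ratios among dim features, which on the pseudocount scale was seen only between pH 7.0 and pH 7.4, for which noise of dim spots is a candidate explanation. The SD of log2 ratios in the dimmest tertile was between 1.457 and 2.442 times that in the brightest tertile over the 3 comparisons. The lowest ratio missed the 1.5 set beforehand. A wider response of weakly expressed genes would also widen the spread, so no value of this ratio could tell it from noise.

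Leaving the 10 bright features out of the total moved the median log2 difference by 0.0623 at pH 7.0 and by -0.0758 at pH 6.7. The larger of these, 0.0758, was under the 0.1 set beforehand, but the median differences themselves were -0.07 and -0.00488, also under that bound, so the bound could not decide whether the bright features set them.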
